A study of Mus musculus with 15 samples.

How the data were processed

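Gene expression was measured by RNA sequencing in mouse T cells from a wild-type group (WT), a model of Kabuki syndrome type 1 (KS1) and a model of Kabuki syndrome type 2 (KS2), with 5 libraries per group and 15 in all. Kabuki syndrome is a developmental disorder whose type 1 form is caused by loss of KMT2D, a histone H3 lysine 4 methyltransferase, and whose type 2 form is caused by loss of KDM6A, a histone H3 lysine 27 demethylase. Per the labels' protocols, cells that had passed a CD19 depletion step were selected with CD90.2 (Thy1.2) microbeads, RNA was extracted with Trizol, polyadenylated RNA was captured, and directional paired-end libraries were sequenced on a HiSeq4000. Per the labels, the mice were of the C57BL/6j strain. The labels disagree on the cell type, because the source field of these samples names CD19-positive B cells while the cell type field names CD90.2-positive T cells. Markers of both lineages were therefore measured in every library.

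The deposited table holds estimated counts per gene, which need not be whole, and 37.3% of its values differ from a whole number, with no tolerance allowed. Per the submitters' processing notes, the tools and builds named are Salmon 0.10 and mm10. The transcript annotation, the step from transcripts to genes and whether the strand was used in counting are not given in the sources used here. Salmon shares reads that match several transcripts by a statistical estimate, so counts of near-identical genes and pseudogenes, and of overlapping genes, are uncertain. The estimated counts were rounded to whole numbers, which moves a value by at most 0.5. The table has 27911 Ensembl gene rows, of which 27430 carry a gene symbol. Columns were matched to samples by name, and 0 columns of per-sample values were left unmatched. Gene coordinates on GRCm38 (mm10) came from GENCODE release M21, in which 27500 of the identifiers were found.

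Totals ran from 20253866 to 29494555 estimated counts per library. Replicates were compared before averaging. Between replicate pairs of a group, the chi-square statistic per gene lay between 8.50 and 83.7, far above sampling noise, and the correlation of log counts lay between 0.967 and 0.980, so no library was treated as a duplicate. The labels do not say whether the libraries of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

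Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr (13631 genes), libraries were scaled by TMM, and a quasi-likelihood model with robust dispersion and group as its only term was fitted to all 15 libraries. The common biological coefficient of variation was 0.199 and the prior degrees of freedom 3.72. Contrasts were KS1 against WT, KS2 against WT and KS2 against KS1, each with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a single gene given without another tool's name comes from this edgeR test. Fold changes are on the log2 scale with a prior count of 0.125, followed by an approximate standard error (SE). The SE was calculated back from the test, as the absolute log2 fold change over the square root of its F statistic. Levels are CPM, the count relative to the TMM-scaled library total, as mean ± SD over the 5 libraries of a group.

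The model, the gene lists, the rule for named genes and most alternative settings were set before the data were examined. The rule names Kmt2d and Kdm6a. In each comparison it names the 10 genes of largest fold change per direction among those past the threshold with a mean of at least 1 CPM over all libraries. Genes without a symbol, predicted genes, pseudogenes and antigen receptor segments are counted but not named. Where fewer than 5 genes passed in a direction, those of smallest p up to 5 are named as not passing. From each list it names up to 4 members that passed, or, where none did, up to 2 of the highest level, and it names the genes called in both models. A gene that this rule would name is not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

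Altogether 35 lists of T cell genes, signalling and stress genes, chromatin regulators and markers of other cell types were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over lists within a comparison. Camera was then run with an estimated correlation, and fry was run as a test of each list on its own, for a shift in one direction and, as its mixed test, for change in either. A list of 5 sex-linked genes had only 2 tested members and no camera value. Summed CPM of the markers of other cells was compared between groups by two-sided exact permutation over all 252 relabellings, for which the smallest possible p is 0.00794. The position of called genes was compared with that of all tested genes by a two-sided Fisher's exact test, in windows of 10 Mb around each targeted gene and over its chromosome. Windows of 5 and 30 Mb were added after the calls had been seen, and adjustment was over all 24 such tests.

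Alternatives were another scaling, other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, a fit of the 10 libraries compared, a term for the replicate number, a term for the number series in the labels, surrogate variables from sva 3.50.0, marker levels as covariates, dispersion without robust estimation, a threshold of 0.1, and each library left out in turn. A covariate for sex was not fitted. The steps were tested on simulated counts of 13631 genes with 50 genes changed at each of 4 fold sizes. In the simulated KS1 against WT comparison edgeR recovered 18% of genes changed 1.3-fold, 50% at 1.5-fold, 72% at 2-fold and 90% at 4-fold, and 1 of 116 calls was false. In the simulated KS2 against WT comparison it recovered 26%, 64%, 76% and 92% at those folds, and 6 of 135 calls were false. DESeq2 gave 12.0% and 14.6% false calls there, and limma-voom 1.74% and 5.30%. Of 31 lists in the simulated KS1 against WT comparison, the raised list was found by camera with both correlations and by fry, and 0 of the lists left unchanged were called. Genes were simulated independently of each other and the lists drawn at random. The simulation therefore does not show how often camera at the preset correlation calls lists whose members vary together. The estimated correlation of the B cell markers, for example, was 0.894 in KS1 against WT.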

Results

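RNA sequencing of CD90.2-selected mouse T cells gave 15 libraries, 5 each from wild-type mice (WT), a Kabuki syndrome type 1 model (KS1) and a Kabuki syndrome type 2 model (KS2). Total estimated counts per library ran from 21471135 to 29494555 in WT, from 21842091 to 25205683 in KS1 and from 20253866 to 26846118 in KS2. Levels are given in CPM as mean ± SD (n = 5). T cell transcripts were abundant in every group: the T cell receptor gene Trbc2 stood at 580 ± 60.7 CPM in WT, 583 ± 100.4 in KS1 and 619 ± 44.9 in KS2, and the T cell kinase gene Lck at 615 ± 62.9, 624 ± 106 and 637 ± 54.2 CPM. Transcripts of B cells were present too, with the class II invariant chain Cd74 at 1676 ± 735, 1525 ± 747 and 1035 ± 300.4 CPM and the immunoglobulin heavy chain Ighm at 916 ± 179, 826 ± 242 and 709 ± 141 CPM. Erythroid markers summed to 16082 ± 11235 CPM in WT, 15168 ± 6597 in KS1 and 12958 ± 3998 in KS2. In WT, pan-T cell genes summed to 6305 CPM, B cell markers to 5704 and macrophage markers to 4980. The selected fraction was therefore mixed, and such sums over unlike genes do not give shares of cells. The first principal component held 18.7% of the variance, and along it libraries 1 and 2 of KS1 lay highest (38.6 and 36.6) and library 1 of WT lowest (-40.1). KS1 1 and 2 also had the highest summed macrophage markers (8125 and 8179 CPM) and dendritic cell markers (1316 and 1328 CPM) of the 15 libraries, and WT 1 the lowest of both (3109 and 539 CPM).

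The models carry changes in Kmt2d or Kdm6a, so these genes were measured first in every library. Kmt2d (ENSMUSG00000048154) lies on chromosome 15 from 98831669 to 98871204 on the minus strand of GRCm38. Its level was 1167 ± 219 CPM in WT, 1028 ± 184 in KS1 and 1147 ± 204 in KS2, and the KS1 against WT log2 fold change was -0.18 (SE 0.15, edgeR adjusted p = 0.626). Kdm6a (ENSMUSG00000037369) lies on chromosome X from 18162575 to 18279936. Its level was 126.02 ± 10.6 CPM in WT, 136 ± 10.8 in KS1 and 122 ± 8.38 in KS2, and the KS2 against WT log2 fold change was -0.04 (SE 0.07, edgeR adjusted p = 0.993). Neither gene passed the test in any of the 3 comparisons. The labels describe no allele, and a count summed over a gene cannot show a change in part of its transcript, so these levels do not check the labels.

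**Figure D1:**
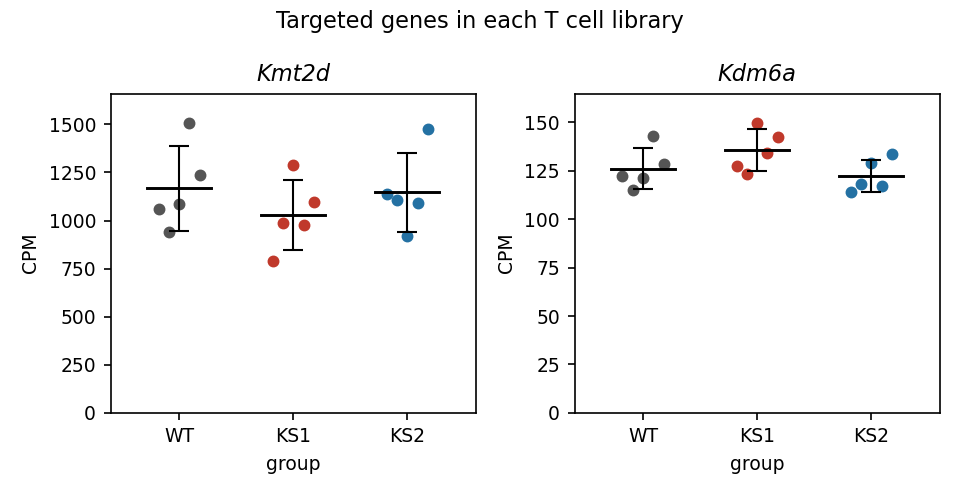
Levels of Kmt2d and Kdm6a in CPM (vertical axes from 0) in each library of the WT, KS1 and KS2 groups, with 1 point per library and bars for the mean ± SD of 5 libraries. The groups overlap for both genes, with Kmt2d at 1167 ± 219 CPM in WT and 1028 ± 184 in KS1, and Kdm6a at 126.02 ± 10.6 CPM in WT and 122 ± 8.38 in KS2.

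The comparison of KS1 with WT asked which transcripts differ in the CD90.2-selected cells of the type 1 model. Itgae, which encodes CD103, fell from 86.6 ± 10.4 to 34.2 ± 8.92 CPM (log2 fold change -1.34, SE 0.16, edgeR adjusted p = 0.000469). Itgb7, whose product pairs with CD103 in an integrin that binds E-cadherin, fell from 802 ± 33.0 to 590 ± 33.2 CPM (-0.44, SE 0.05, edgeR adjusted p = 0.000388). Ggt1, a gamma-glutamyltransferase, fell from 32.2 ± 5.4 to 12.5 ± 2.49 CPM (-1.36, SE 0.14, edgeR adjusted p = 0.000155), and Eya2, a phosphatase and transcriptional coactivator, from 21.6 ± 2.88 to 9.05 ± 1.5 CPM (-1.25, SE 0.13, edgeR adjusted p = 0.000154). Osbpl6, of the oxysterol-binding protein family, rose from 0.954 ± 0.327 to 5.26 ± 1.54 CPM (2.45, SE 0.26, edgeR adjusted p = 0.000201), and Map2, a microtubule-associated protein, from 0.903 ± 0.322 to 4.49 ± 1.04 CPM (2.30, SE 0.30, edgeR adjusted p = 0.00108). The costimulatory receptor gene Icos rose from 55.0 ± 3.96 to 79.5 ± 12 CPM (0.53, SE 0.09, edgeR adjusted p = 0.0063).

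Other large increases in KS1 were at genes of low level. Slc16a2, a thyroid hormone transporter, rose from 0.685 to 2.89 CPM (log2 fold change 2.06), the Wnt receptor Fzd1 from 0.600 to 3.10 CPM (2.34), the proapoptotic gene Bik from 0.613 to 2.35 CPM (1.93) and the membrane metalloproteinase Mmp14 from 0.781 to 2.86 CPM (1.86). Other large decreases were in Igsf23 (8.45 to 2.27 CPM, -1.89), the cytochrome P450 gene Cyp2s1 (15.5 to 6.24 CPM, -1.31), Wfikkn2 (8.82 to 3.64 CPM, -1.28) and Ksr2, a scaffold of the MAP kinase pathway (11.9 to 5.05 CPM, -1.23). The cell-cycle phosphatase gene Cdc25b fell from 123 ± 9.61 to 84.6 ± 5.02 CPM (-0.54, SE 0.06, edgeR adjusted p = 0.000201).

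In total 176 of 13631 genes passed edgeR's test in KS1 against WT, 75 higher and 101 lower, with a median absolute log2 fold change of 0.68. Of these, 45 changed more than 2-fold, and in 146, which were selected for such a difference, the ranges of the groups did not overlap. Over all 13631 tested genes they did not overlap in 416 (3.05%), where chance gives 0.794%. Without p-value adjustment 1941 genes lay under 0.05. The count was sensitive to single libraries: it was 85 without WT library 1, 110 without WT 4, 89 without WT 5, 108 without KS1 library 1, 90 without KS1 2 and 97 without KS1 3, and 92 without both KS1 1 and 2.

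**Figure D2:**
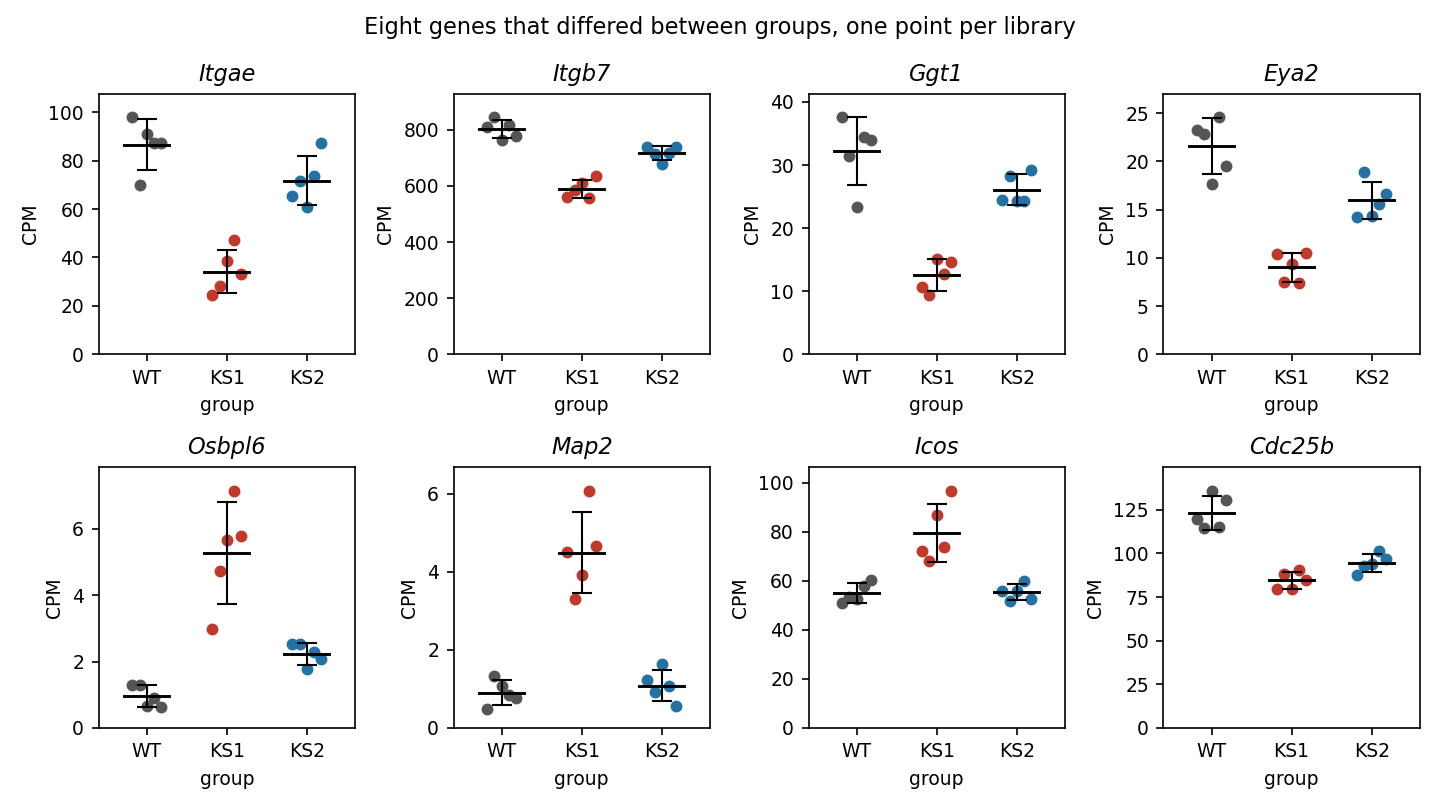
Levels in CPM (vertical axes from 0) of 8 named genes in each library of WT, KS1 and KS2, with 1 point per library and bars for the mean ± SD of 5 libraries. Itgae, Itgb7, Ggt1, Eya2 and Cdc25b are lower in KS1 than in WT, as for Itgae at 34.2 against 86.6 CPM, and Osbpl6, Map2 and Icos are higher, as for Icos at 79.5 against 55.0 CPM.

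Several other named genes passed in KS1 against WT, but lost the call when single libraries were left out. Gjb2, a gap junction protein, rose from 1.72 ± 0.683 to 8.30 ± 6.08 CPM (log2 fold change 2.25), and was lost without WT 1, WT 3, WT 4, WT 5, KS1 1 or KS1 2 (edgeR adjusted p 0.0593 to 0.0948). Adgrl3 (1.77), an adhesion receptor whose group ranges overlapped, was lost without WT 1, WT 2, WT 4, KS1 1 or KS1 2 (edgeR adjusted p 0.055 to 0.0846). Lrig3 (1.68) was lost without WT 1, WT 3, WT 5, KS1 2, KS1 3 or KS1 4 (edgeR adjusted p 0.0502 to 0.0684), and Maneal (1.45) without KS1 3 (edgeR adjusted p = 0.0502). Among genes that fell, Sp6 (-1.43) was lost without WT 1, WT 4, WT 5, KS1 2, KS1 3 or KS1 5 (edgeR adjusted p 0.0542 to 0.0836). The laminin-binding integrin gene Itga7 (-1.31) was lost without KS1 2 (edgeR adjusted p = 0.0526). Gpr34 (-1.27), a lysophosphatidylserine receptor, was lost without WT 1, KS1 1 or KS1 3 (edgeR adjusted p 0.0542 to 0.0554).

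Among lists fixed in advance, the 25 homing receptors and integrins had 2 members that fell, Itgae and Itgb7, and 3 with Ccr10 (-1.11) when adjusted over the list alone. Of 15 regulatory T cell genes, Itgae fell, and Tnfrsf18 (-0.31) fell with it when adjusted over the list alone. Foxp3, which defines that lineage, stood at 11.96 ± 1.79 CPM in WT and 13.7 ± 3.39 in KS1 (0.19, edgeR adjusted p = 0.630). Icos was the member that rose of 18 activation and checkpoint genes, of 7 CD4 lineage genes and of 9 follicular helper genes, which share it. Adjusted over the list alone, the activation list had 1 that rose and 2 that fell (Tnfrsf9 at -0.90 and Tnfrsf18), and the other 2 lists kept 1 that rose. The T-box factor gene Eomes rose (0.54, 49.0 ± 8.81 to 71.6 ± 9.82 CPM). It is shared by the lists of CD8 lineage, effector and age-associated genes, of which 1 member of 7, 1 of 21 and 1 of 17 rose, with equal counts when adjusted over the list alone. In the effector list the granzyme gene Gzmm fell (-0.72, 5.86 ± 0.621 to 3.56 ± 0.677 CPM), by both adjustments. The Eomes call was lost without WT 1, WT 3, WT 4, WT 5, KS1 1, KS1 2 or KS1 5 (edgeR adjusted p 0.0539 to 0.0871). The Gzmm call was lost on omission of any library other than KS2 4 and KS2 5 (edgeR adjusted p 0.0566 to 0.109). CD8 T cell transcripts were near their WT level, with Cd8a at a log2 fold change of -0.03 and Cd8b1 at -0.11 (edgeR adjusted p = 0.949 and 0.797), as were the naive T cell genes Klf2 (0.11) and Tcf7 (0.01). Cd4, chosen after its values were seen, stood at 303 ± 36.6 CPM in WT and 239 ± 54.4 in KS1 (-0.34, SE 0.13, edgeR adjusted p = 0.237). Of the 7 CD4 lineage genes 5 were negative and 2 positive.

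Of 16 genes of the COMPASS and KMT2C/D complexes, Ncoa6, a subunit of the KMT2D complex, rose from 126.3 ± 7.71 to 149 ± 7.58 CPM (0.23, edgeR adjusted p = 0.0439), by both adjustments, and the call was kept only on omission of WT 3, KS1 4 or KS2 3 (edgeR adjusted p otherwise 0.0562 to 0.112). Of 13 H3K27 methylation genes none passed over all genes with edgeR, DESeq2 or limma-voom, while 7 had an unadjusted p under 0.05. Adjusted over the list alone, the demethylase gene Kdm6b (0.58) and Epop (0.36) were higher and Ezh1 (-0.16) and Mtf2 (-0.28) lower. Of 13 mitochondrially encoded genes the complex I subunit mt-Nd3 rose from 108 ± 29.8 to 197 ± 35.9 CPM (0.87, edgeR adjusted p = 0.0455), by both adjustments, and the call was kept only without WT 3 or KS2 5 (edgeR adjusted p otherwise 0.0554 to 0.121). Of 95 cytosolic ribosomal proteins Rpl3 fell from 1592 ± 182 to 920 ± 75.4 CPM (-0.79), by both adjustments, and its reads may be split with a pseudogene.

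As whole lists, 6 of those tested with camera differed in KS1 against WT at the preset correlation, and none of the 6 with an estimated correlation (adjusted p = 0.893 for each with an estimated correlation). The 27 immediate early and T cell receptor-induced genes were shifted up (24 positive, camera adjusted p = 0.000151), with Nr4a1 at 751 ± 494 CPM in WT and 1469 ± 518 in KS1 (0.97, edgeR adjusted p = 0.388) and Junb at a log2 fold change of 0.30. The 25 heat shock and unfolded protein genes were shifted up too (20 positive, camera adjusted p = 0.00273), with Hspa8 at 0.18 and Hsp90ab1 at 0.22. Both lists held in every omission of a library. Beside them, 16 of 19 macrophage markers (median 0.26) and 12 of 16 neutrophil markers (median 0.68) were positive in KS1 (camera adjusted p = 0.234 for each). Hypoxia and glycolysis genes were shifted up (23 of 30 positive, camera adjusted p = 0.0305), but not without WT 1 (0.111), KS1 1 (0.163) or KS1 2 (0.126). Natural killer cell markers were shifted up (13 of 15 positive, camera adjusted p = 0.0369), but not without WT 3 (0.328), WT 4 (0.159), KS1 1 (0.294), KS1 5 (0.141) or KS2 1 (0.0538). Regulatory T cell genes were shifted down (camera adjusted p = 0.0305, mean log2 fold change -0.15, median -0.03), but not without WT 2 (0.0591), WT 3 (0.0913) or KS1 1 (0.108). B cell markers were shifted down (22 of 22 negative, camera adjusted p = 0.0246), but not without WT 3 (0.352), KS1 3 (0.104) or KS1 5 (0.538). In the immediate early, heat shock, hypoxia, natural killer and B cell lists no member passed over all genes or over the list alone with edgeR. At an unadjusted p under 0.05 these lists had 5, 7, 6, 2 and 1 members, DESeq2 called 1 B cell marker, and limma-voom called 0. Without KS1 libraries 1 and 2 the immediate early list (camera adjusted p = 0.0344) and the B cell list (camera adjusted p = 2.36e-06) kept their calls, and the other 4 did not. With fry's mixed test, for change in either direction, 6 lists passed, including homing receptors and regulatory T cell genes (fry adjusted p = 3.84e-06 for each), activation genes (3.18e-05) and H3K27 methylation genes (6.33e-05).

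Genes called in KS1 were more frequent on chromosome 15, which carries Kmt2d, than elsewhere, but the excess of called genes within 10 Mb of Kmt2d did not pass after adjustment. Of 143 tested genes within 10 Mb of Kmt2d, 5 were called (Fisher's exact p = 0.0389, adjusted over 24 position tests 0.0778), and of 500 on chromosome 15, 17 were called (Fisher's exact p = 0.000282, adjusted 0.00135). The chromosome 15 excess held in every omission of a single library, but not with a block for the replicate number (0.0893), a term for the label number series (0.0649), without KS1 1 and 2 (0.0846) or with label numbers under 100 alone (0.168). Within 30 Mb, a window chosen after the calls were seen, 16 of 355 were called (Fisher's exact p = 1.59e-05, adjusted 0.000191), and within 5 Mb, 3 of 111 (Fisher's exact p = 0.176). The 10 Mb excess passed 0.05 or not depending on the library left out, with a range of 0.0141 to 0.0970. It lay over 0.05 without WT 1, WT 2, WT 5, KS1 3, KS1 5, KS2 2, KS2 3 or KS2 4 (0.0555 to 0.0970). Genes with an unadjusted p under 0.05 in KS1 made up 33 of the 143 within 10 Mb (23.1% against 14.2% elsewhere, Fisher's exact p = 0.00523) and 28 of the 111 within 5 Mb (Fisher's exact p = 0.00234), both without adjustment over tests. In KS2 against WT edgeR called 0 genes in these windows, where 13 of the 143 within 10 Mb had an unadjusted p under 0.05 (9.09% against 5.87% elsewhere, Fisher's exact p = 0.107).

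Of the 17 genes called on chromosome 15, 8 were higher and 9 lower in KS1, 16 lay on the lower-coordinate side of Kmt2d, and 12 lay more than 10 Mb from it. Most of the chromosome is on that side, since Kmt2d lies near its high-coordinate end. The share of tested genes on that side was not computed, and 143 of the 500 tested lay within 10 Mb. Itgb7 lay 3.37 Mb above Kmt2d. Prickle1, a planar cell polarity gene, rose by a log2 fold change of 1.27 (4.53 ± 0.838 to 10.9 ± 2.18 CPM, edgeR adjusted p = 0.000645). Apobec3, a cytidine deaminase that restricts retroviruses, was chosen after its values were seen. It fell from 223 ± 16.7 to 119 ± 12.8 CPM (-0.90, edgeR adjusted p = 3.71e-05), and its annotated end overlaps that of Cbx7 on the opposite strand (-0.47), so reads may be shared. Rpl3 lies at 80077791 to 80091868. Its processed pseudogene Rpl3-ps1, on chromosome X from 13202571 to 13203780, was at 0.256 ± 0.242 CPM in WT, 563 ± 36.7 in KS1 and 0.672 ± 0.319 in KS2 (KS1 against WT 11.18, edgeR adjusted p = 1.42e-10), and was also chosen after its values were seen. Rpl3-ps1 held 38.0 ± 0.73% of the summed counts of both genes in KS1, against 0.0155% in WT and 0.0414% in KS2. The sum itself differed by -0.10 (SE 0.09, edgeR adjusted p = 0.676), so the separate values of Rpl3 and Rpl3-ps1 are uncertain.

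**Figure D3:**
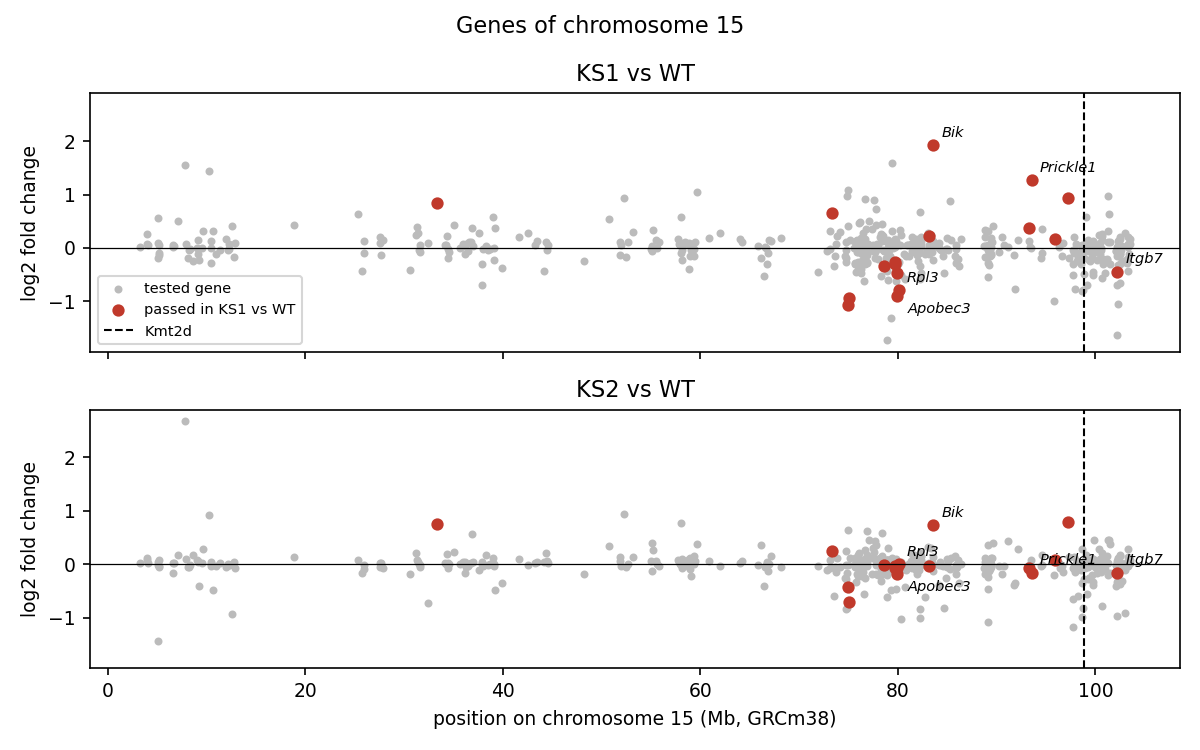
Log2 fold changes (vertical axes) of tested genes along chromosome 15 (horizontal axis, Mb on GRCm38) for KS1 against WT and for KS2 against WT, with genes that passed in KS1 against WT in red, other tested genes in grey and Kmt2d as a dashed line. The 17 genes in red lie mostly on the lower-coordinate side of Kmt2d, which holds most of the chromosome, and Apobec3 stands at -0.90 in KS1 and -0.19 in KS2.

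Called genes were also frequent near Kdm6a in KS1 with edgeR, although that model is named for Kmt2d. Of 43 tested genes within 10 Mb of Kdm6a, 5 were called (Fisher's exact p = 0.000226, adjusted over 24 tests 0.00135), and of 467 on chromosome X, 14 (Fisher's exact p = 0.00514, adjusted 0.0154). An excess of genes with an unadjusted p under 0.05 did not pass, at 20.9% within 10 Mb against 14.2% elsewhere (Fisher's exact p = 0.194) and 13.3% on chromosome X against 14.3% (Fisher's exact p = 0.590). The 10 Mb excess of calls was lost with DESeq2 (0.181), and that on chromosome X without a filter on low counts (0.231), with the label number term (0.0562), surrogate variables (0.578), a threshold of 0.1 (0.113), a macrophage covariate (0.0990) or 3 marker covariates (0.259). The excess on chromosome X also lay over 0.05 without WT 1, WT 4, WT 5, KS1 1, KS1 3, KS1 4 or KS2 3 (0.0561 to 0.153). The 5, named after their values were seen, were Rpl3-ps1, Gpr34 and B630019K06Rik (0.92), the monoamine oxidase gene Maob, which rose from 0.262 to 1.56 CPM (2.50), and the pseudogene Gm5124, which rose from 1.60 to 5.03 CPM (1.64). Rpl3-ps1 is counted here although its reads may come from Rpl3 on chromosome 15, and the excess was not tested without it. In the same windows edgeR called 0 genes in KS2 against WT, and 4 of the 43 had an unadjusted p under 0.05.

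The comparison of KS2 with WT asked the same question of the type 2 model. Itih5, of the family of hyaluronan-binding inhibitor heavy chains, fell from 13.2 ± 1.16 to 6.32 ± 0.944 CPM (log2 fold change -1.06, SE 0.16, edgeR adjusted p = 0.0349). The ectonucleotidase gene Enpp1 fell from 20.0 ± 2.31 to 11.9 ± 0.625 CPM (-0.74, SE 0.11, edgeR adjusted p = 0.0349), and Cdc25b from 123 ± 9.61 to 94.5 ± 4.96 CPM (-0.38, SE 0.06, edgeR adjusted p = 0.0462). These 3 genes were the only ones called by edgeR, and their group ranges did not overlap, as in 183 (1.34%) of all tested genes, where chance gives 0.794%. Next by p, without passing, were Syt6, a synaptotagmin, at 1.33 ± 0.599 CPM in WT and 4.90 ± 1.76 in KS2 (1.87, edgeR adjusted p = 0.0562), Bbs9 (-0.58, edgeR adjusted p = 0.0553), Ppp1r16b (-0.32, edgeR adjusted p = 0.0597), Plekha8 (0.78, edgeR adjusted p = 0.0702), Igfbp4 (0.51), Maged1 (0.88) and Fam174b (0.56), the last 3 at an edgeR adjusted p of 0.119.

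No gene was called higher in KS2 than in WT by edgeR, while DESeq2 called 24 higher and 41 lower, limma-voom called 3 higher and 9 lower, and 801 genes lay under an unadjusted p of 0.05 in edgeR. The calls rested on most single libraries. Itih5 kept its call only without WT 2, KS1 1, KS1 3 or KS2 3 (edgeR adjusted p otherwise 0.051 to 0.141), Enpp1 only without WT 2, KS1 1 or KS1 3 (0.051 to 0.141) and Cdc25b only without WT 2 (0.0545 to 0.141). Without WT 2 the count was 7, and it was 0 without WT 1, WT 3, WT 4, WT 5, KS1 2, KS1 4, KS1 5, KS2 1, KS2 2, KS2 4 or KS2 5.

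B cell markers were shifted down in KS2 (22 of 22 negative, camera adjusted p = 2.62e-15, adjusted p = 0.672 with an estimated correlation), with Cd74 at 1035 ± 300.4 CPM against 1676 ± 735 in WT (log2 fold change -0.70, edgeR adjusted p = 0.884). Plasma cell markers were shifted down (9 of 10 negative, camera adjusted p = 0.00568, adjusted p = 0.672 with an estimated correlation), and both lists held in every omission. Interferon-stimulated genes were shifted up (32 of 39 positive, camera adjusted p = 0.00568, adjusted p = 0.994 with an estimated correlation), with Ifi213 at 313 ± 48.8 CPM in WT and 349 ± 40.7 in KS2, but not without WT 3 (0.0715), WT 5 (0.118) or KS2 1 (0.600). Proliferation genes were shifted down (25 of 30 negative, camera adjusted p = 0.0172, adjusted p = 0.672 with an estimated correlation), with Mcm7 at 81.5 ± 6.44 and 77.1 ± 6.42 CPM, but not without WT 2 (0.533) or KS2 2 (0.169). Single members of these 4 lists passed neither over all genes nor over the list alone with edgeR, nor with DESeq2 or limma-voom, and 5, 3, 3 and 0 of them had an unadjusted p under 0.05. Adjusted over the list alone, Igfbp4 of 17 naive T cell genes and Col1a1 (1.68) of 4 stromal genes tested were higher. Summed over markers, B cell transcripts were 5704 ± 2089 CPM in WT, 5057 ± 2278 in KS1 and 3640 ± 1063 in KS2 (KS2 against WT two-sided exact permutation p = 0.0714, adjusted over lists 0.370). Macrophage markers summed to 4980 ± 1945, 6094 ± 1896 and 5720 ± 1465 CPM. No list passed on its sum after adjustment, but with a smallest possible p of 0.00794 and 14 lists a single list could not have passed in this design. The 24 pan-T cell genes summed to 6305 ± 576, 6196 ± 969 and 6439 ± 393 CPM.

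The models were then compared with each other. In KS2 relative to KS1, Itgae (34.2 ± 8.92 to 71.7 ± 10.1 CPM, log2 fold change 1.07, SE 0.16, edgeR adjusted p = 0.0068) and Ggt1 (12.5 ± 2.49 to 26.1 ± 2.41 CPM, 1.06, SE 0.14, edgeR adjusted p = 0.00302) were higher. So were Syt6 (1.34 ± 0.225 to 4.90 ± 1.76 CPM, 1.87, SE 0.31, edgeR adjusted p = 0.0132) and Adamtsl4 (0.84, edgeR adjusted p = 0.00906). Map2 was lower (4.49 ± 1.04 to 1.08 ± 0.403 CPM, -2.05, SE 0.30, edgeR adjusted p = 0.0061), as were Prickle1 (10.9 ± 2.18 to 4.05 ± 0.337 CPM, -1.43, SE 0.16, edgeR adjusted p = 0.000906), mt-Nd3 (197 ± 35.9 to 73.2 ± 15 CPM, -1.43, edgeR adjusted p = 0.0061), the tetraspanin gene Tspan9 (-1.08, edgeR adjusted p = 0.0132) and Icos (-0.53, edgeR adjusted p = 0.0132). Rpl3 was higher by 0.79 (edgeR adjusted p = 0.00116), with the uncertainty given for its pseudogene. These calls held in every omission of a single library.

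Altogether 66 genes passed edgeR's test in KS2 against KS1, 31 higher and 35 lower, 18 of them by more than 2-fold. In 63 of them, selected for such a difference, the ranges of the groups did not overlap. Over all tested genes they did not overlap in 372 (2.73%), where chance gives 0.794%, and 1537 genes lay under an unadjusted p of 0.05. The count was 29 without KS1 library 1, 35 without KS1 3, 24 without KS2 library 1, 33 without KS2 2, 33 without KS2 4 and 38 without KS2 5, and 37 without both KS1 1 and 2. With a term for the label number series it was 4. With that term all 66 genes kept their sign and an unadjusted p under 0.05, the median ratio of their log2 fold changes to those without it was 1.00 (0.552 to 1.37), and their median SE went from 0.11 to 0.15. Within 10 Mb of Kmt2d 5 of 143 tested genes were called (Fisher's exact p = 0.000653, adjusted 0.00261). The KS1 libraries are those of KS1 against WT, so this excess is not separate evidence. It was not examined under the alternative settings.

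Other named calls of this comparison depended on single libraries. Among genes higher in KS2 than in KS1, Gpr34 (log2 fold change 1.42) was lost without KS1 1, KS1 3, KS2 1, KS2 2 or KS2 4 (edgeR adjusted p 0.0516 to 0.061). Gpr83 (1.42, 3.74 ± 1.15 to 10.02 ± 2.38 CPM) was lost without KS1 1, KS1 2, KS1 3, KS2 1, KS2 2 or KS2 4 (edgeR adjusted p 0.0546 to 0.0736). The lysophosphatidylinositol receptor gene Gpr55 (1.09) was lost without KS1 1, KS1 3, KS1 5, KS2 1 or KS2 2 (edgeR adjusted p 0.0509 to 0.0692), and the lysophosphatidic acid receptor gene Lpar5 (0.87) without KS2 1 (edgeR adjusted p = 0.0509). Gtf2ird1 (0.98) kept its call only without WT 1, WT 2 or WT 3 (edgeR adjusted p otherwise 0.0595 to 0.128), and Itgb7 (0.28) was lost without KS1 1, KS1 4, KS2 1, KS2 2, KS2 4 or KS2 5 (edgeR adjusted p 0.0535 to 0.0767).

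Among genes lower in KS2 than in KS1, Slc16a2 (log2 fold change -1.52) was lost without KS1 1, KS1 2, KS1 3, KS1 5, KS2 1, KS2 2 or KS2 4 (edgeR adjusted p 0.0504 to 0.0859). Eomes (-0.65) was lost without KS1 1, KS2 1, KS2 2, KS2 4 or KS2 5 (edgeR adjusted p 0.053 to 0.0584), and Ildr1 (-0.99) without KS1 3, KS2 1, KS2 2 or KS2 5 (edgeR adjusted p 0.0584 to 0.0767). Osbpl6 (-1.23) kept its call only without WT 1, WT 2, WT 3, WT 5 or KS1 1 (edgeR adjusted p otherwise 0.0519 to 0.101), and the proteoglycan gene Prg4 (-1.01) only without WT 1 or WT 3 (0.0504 to 0.118). The MAP kinase phosphatase gene Dusp4 (-0.98) kept it only without WT 3, WT 4 or KS2 3 (0.0513 to 0.1248), and Zbtb10 (-0.82) only without WT 1, WT 3, WT 4, KS1 4 or KS2 3 (0.0533 to 0.132).

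As whole lists, 6 passed camera in KS2 against KS1, all shifted down in KS2 relative to KS1, and none of the 6 with an estimated correlation. Immediate early genes had 25 of 27 negative (camera adjusted p = 8.58e-07, adjusted p = 0.818 with an estimated correlation), with Junb at 2094 ± 327 CPM in KS1 and 1516 ± 743 in KS2 (-0.47, edgeR adjusted p = 0.629). Heat shock genes had 23 of 25 negative (camera adjusted p = 0.000196, adjusted p = 0.818 with an estimated correlation), and both lists held in every omission. In KS2 against WT neither of these lists was shifted, with 14 of 27 and 13 of 25 positive (camera adjusted p = 0.893 and 0.918). Both were shifted up in KS1 against WT, which uses the same KS1 libraries. Effector T cell genes had 17 of 21 negative (camera adjusted p = 0.0017, adjusted p = 0.818 with an estimated correlation), but not without KS1 1 (0.0512). Beside them, 13 of 15 natural killer markers (median -0.36, camera adjusted p = 0.0581), 12 of 14 dendritic and 11 of 16 neutrophil markers were negative. Platelet and stromal markers went the other way, with 8 of 11 and 4 of 4 positive. B cell markers had 21 of 22 negative (camera adjusted p = 0.00593, adjusted p = 0.848 with an estimated correlation), but not without KS1 1 (0.248), KS1 4 (0.203), KS2 1 (0.0886) or KS2 5 (0.134). Hypoxia and NF-kB genes each had a camera adjusted p of 0.0414 (adjusted p = 0.818 with an estimated correlation). The hypoxia list was lost without WT 3, KS1 1, KS1 2, KS2 2 or KS2 4 (0.0647 to 0.179), and the NF-kB list without WT 2, WT 3, KS1 1, KS1 2, KS2 1, KS2 2 or KS2 4 (0.0594 to 0.185). Without both KS1 1 and KS1 2 the immediate early list alone of the 6 kept its call. Of 5 X-inactivation escape genes all were negative (fry adjusted p = 0.0158, camera adjusted p = 0.0801, or 0.818 with an estimated correlation), with Ddx3x at 605 ± 84.8 CPM in KS1 and 514 ± 72.4 in KS2 (-0.23, edgeR adjusted p = 0.391). Kdm6a is 1 of the 5. Against WT, 4 of the 5 were negative in KS2 (median -0.01, fry adjusted p = 0.996), and 5 were positive in KS1 (median 0.11, fry adjusted p = 0.0581). Of 15 regulatory T cell genes 2 passed as higher, Itgae and Gpr83, and 3 when adjusted over the list alone, with Izumo1r (0.45).

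Whether both models changed the same genes was asked from the calls and from all fold changes. With edgeR and TMM scaling Cdc25b was the only gene called in both models, lower in each, while 0 genes were shared with RLE scaling or a replicate block and 71 with surrogate variables. Independent lists would share 0.0222 genes. Simulated unchanged groups gave almost no calls to share, so they set no chance value for this overlap, and part of it may come from the shared WT libraries. Cdc25b kept its KS1 call in every omission of a library, but its KS2 call only without WT 2 (edgeR adjusted p otherwise 0.0545 to 0.141). Of the 176 genes called in KS1, 151 (85.8%) had the same sign in KS2, with a median KS2 to KS1 ratio of 0.343. The fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.487 and a Spearman rho of 0.455. Unchanged groups simulated against the same WT libraries gave a mean r of 0.503 (0.429 to 0.559) and a mean rho of 0.451. The covariance was 0.0547 against a simulated mean of 0.0451 (0.0380 to 0.0541), a difference of 0.00965. Genes were simulated independently of each other here too, so the simulated ranges may be too narrow. With the WT libraries split between the comparisons, the mean r over 20 splits was 0.0729 (-0.0761 to 0.176) and the mean covariance 0.0125 (-0.0147 to 0.0303). At an unadjusted p under 0.05 in both comparisons, 345 genes had the same direction against a simulated 134 (107 to 159), and 6 had opposite directions. The simulated count is no chance value for this number either, because both groups were simulated as unchanged. In the data 1941 genes lay under 0.05 in KS1 and 801 in KS2, where unchanged groups would give 682 in each. Of the genes with an unadjusted p under 0.05 in KS1, 81.3% had the same sign in KS2, against 89.3% in simulations and 57.0% with split WT libraries.

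**Figure D4:**
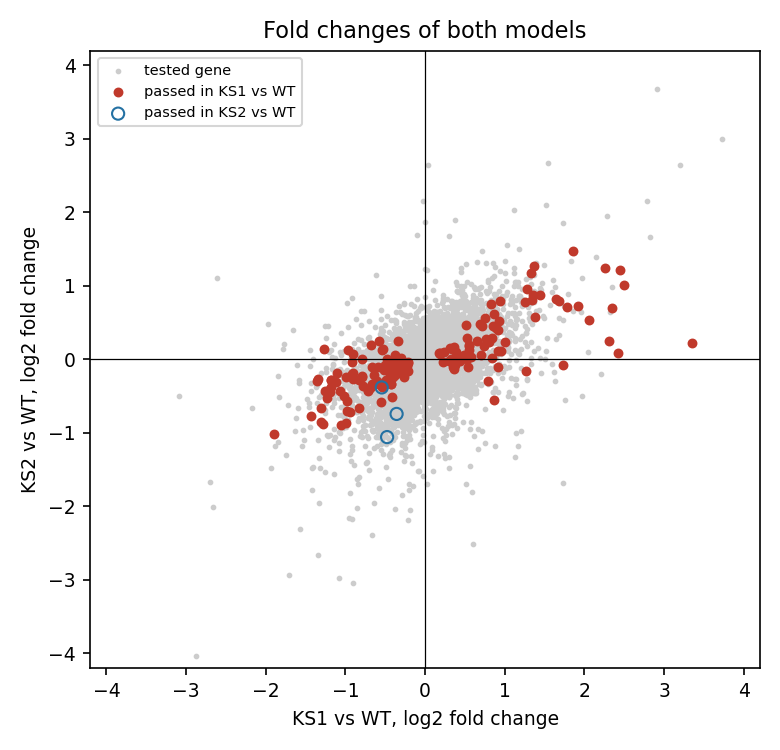
Log2 fold change of each tested gene in KS1 against WT (horizontal axis) and in KS2 against WT (vertical axis), with genes that passed in KS1 in red, genes that passed in KS2 as blue rings and other tested genes in grey. Of the 176 genes in red, 151 have the same sign on both axes, and 3 genes lie outside the axes, which end at 4.2 in either direction.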

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

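The tests of flanking DNA, of reads shared by Rpl3 and its pseudogene, of the share of CD8 T cells and of the share of regulatory T cells were chosen only after the results they bear on had been seen, and the macrophage term in the test of admixed cells was added after the data had been seen.

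The groups of the 2 models differed from each other: 66 genes passed edgeR's test of KS2 against KS1, which is also the test of the difference between their differences from WT. With a term for the label number series the count was 4, while all 66 kept their sign, with a median ratio of log2 fold changes of 1.00 (0.552 to 1.37), and their median SE went from 0.11 to 0.15, since 0 KS1 and 4 KS2 libraries have numbers of 100 or above. Of 100 splits drawn from those possible of the 10 libraries, 2 gave as many genes, the real split included, and the highest other count was 210. That share is under the 5% set for this test, without adjustment over the 3 comparisons. A split with several times the real count points to a structure of the samples beyond their group. Among 180 groups of 5 values, from 45 genes and 14 marker lists and the other values measured per library, 4 held a value apart from the rest by Dixon's criterion, where chance flags about 1 in 20 groups, or 9 of these. Neutrophil markers summed to 1273 CPM in WT library 2 against 467 to 677 in the other WT libraries. Erythroid markers summed to 3571 CPM in KS1 library 5 against 16721 to 19818 in the other KS1 libraries. Platelet markers summed to 318 CPM in KS2 library 5 against 123 to 149 in the other KS2 libraries. Tspan9 stood at 10.9 CPM in KS2 library 3 against 16.8 to 18.3 in the other KS2 libraries.

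Genes called in KS1 were frequent on chromosome 15. Within 10 Mb of Kmt2d 5 of 143 tested genes were called, and the excess did not pass after adjustment (Fisher's exact p = 0.0389, adjusted 0.0778). An excess passed within 30 Mb, a window chosen after the calls were seen (16 of 355, Fisher's exact test, adjusted 0.000191). It also passed within 10 Mb in KS2 against KS1 (5 of 143, adjusted 0.00261), which uses the same KS1 libraries and so is not separate evidence. Within 10 Mb of Kmt2d 33 genes lay under an unadjusted p of 0.05 in KS1 (Fisher's exact p = 0.00523). DNA of another strain carried along with the Kmt2d allele stays open as a candidate explanation, because the excess itself prompted it, the 3 calls of KS2 were too few to show an excess or its lack (13 genes there under an unadjusted p of 0.05, Fisher's exact p = 0.107), and no genotype was examined. Calls were also frequent near Kdm6a on chromosome X, at 5 of 43 genes (Fisher's exact p = 0.000226). That excess was lost with DESeq2 (0.181) and not passed by genes at an unadjusted p under 0.05 (0.194). Rpl3-ps1 is among the 5, and its counts may be reads of Rpl3 on chromosome 15. Its call therefore does not speak against flanking DNA. Whether flanking DNA could account for the other calls there was not tested. Reads shared with the pseudogene Rpl3-ps1 may account for the Rpl3 call on chromosome 15, since the summed counts differed by -0.10 (SE 0.09) while the genes taken alone were called in opposite directions. Sharing alone does not say why Rpl3-ps1 held 38.0% of the summed counts in KS1, 0.0155% in WT and 0.0414% in KS2. A difference in sequence between the groups was not examined, so sharing of reads and flanking DNA may both hold. A direct effect of the Kmt2d change on genes of chromosome 15 stays open and was not tested.

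Itgae was lower in KS1 with a log2 fold change of -1.34 (SE 0.16). The tables argue against a lower share of CD8 T cells, since the mean of Cd8a and Cd8b1 lay 1.27 above the Itgae value (SE 0.187), and against a lower share of regulatory T cells, since the median of 14 other genes of that list lay 1.32 above it (SD of those genes 0.345). They argue against a varying admixture of B cells or macrophages as the whole cause, since with both marker levels as covariates the Itgae value was -1.27 (SE 0.143, edgeR adjusted p = 0.0005). A change in a smaller T cell subset that carries CD103 stays open, because no list here marks it. A lower level of Itgae per cell in the KS1 model may be the cause, as a hypothesis found and examined on the same data.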

How the results depend on the processing

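The marker covariates other than B cells, the omission of KS1 libraries 1 and 2, the omission of genes near Kmt2d and the choices by label number were added only after the data had been seen.

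The counts of called genes moved with the setting, in KS1 against WT, KS2 against WT and KS2 against KS1 in that order, from 176, 3 and 66. They were 173, 2 and 65 with RLE scaling, 143, 6 and 60 without a filter, 188, 4 and 61 with a filter of 1 CPM, 491, 65 and 267 with DESeq2, 120, 12 and 124 with limma-voom, 78, 3 and 51 with the 10 libraries compared, 635, 155 and 409 with surrogate variables, 224, 0 and 62 with a B cell covariate, 172, 2 and 67 without robust dispersion, 381, 10 and 145 at 0.1, 350, 25 and 317 with a macrophage covariate, 502, 14 and 253 with 3 marker covariates, and 109, 0 and 4 with a term for the label number. Label numbers of 100 or above belong to 0 KS1, 4 KS2 and 2 WT libraries, so that term overlaps with group and raises the errors. With label numbers under 100 alone KS1 against WT gave 21, and with those of 100 or above KS2 against WT gave 0. Without KS1 1 and 2 the counts for KS1 against WT and KS2 against KS1 were 92 and 37, and without genes within 30 Mb of Kmt2d the first was 154. Of the 176 genes, 175 were called by DESeq2, 73 with the 10 libraries compared and 73 without KS1 1 and 2. Beside the counts of 0 in KS2 against WT edgeR gave 1027 genes under an unadjusted p of 0.05 with the B cell term, 646 with the label number term and 546 with label numbers of 100 or above.

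Replicate numbers are shared between groups but do not pair the samples: 3 of 15 same-numbered pairs correlated over 0.1 (-0.256 to 0.173), and 2 libraries correlated best with one of their own number. With the replicate number as a block the counts were 95, 0 and 37 (85 of the 176 called genes shared, 768 genes under an unadjusted p of 0.05 in KS2), the overlap of calls was 0, and the position tests gave 0.0793 within 10 Mb of Kmt2d and 0.0893 on chromosome 15. The overlap was 0 with RLE scaling and 71 with surrogate variables, and the correlation of models 0.454 with 3 markers.

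The number of lists past the threshold was 0 in each comparison with an estimated correlation, and 0, 0 and 1 with fry in 1 direction (6, 0 and 6 with its mixed test). It was 10 in KS1 and 9 in KS2 with surrogate variables, and in KS2 against KS1 11 with the label number term and 3 without KS1 1 and 2. The p within 10 Mb of Kmt2d was 0.0561 without a filter, 0.0504 with the 1 CPM filter, 0.0512 with 10 libraries, 0.108 with the label number term, 0.0722 without KS1 1 and 2 and 1 with low label numbers. On chromosome 15 it was 0.0649, 0.0846 and 0.168 in the last 3 of these. Within 10 Mb of Kdm6a it was 0.181 with DESeq2. On chromosome X it was 0.231 without a filter, 0.0562 with the label number term, 0.578 with surrogate variables, 0.113 at 0.1, 0.0990 with macrophage and 0.259 with 3 markers. Kmt2d in KS2 turned to 0.133 with the label number term, 0.0257 with macrophage markers and 0.0949 with high label numbers, and Kdm6a in KS2 to 0.0179 and 0.0169 in the first and last of these. Kmt2d in KS2 against KS1 turned to -0.0773 with 3 markers. None of these was called. Where fewer libraries or genes were fitted that may account for part of the change, but the cause was not tested in any setting.

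Leaving out each library gave 85 to 183, 0 to 7 and 24 to 90 genes, 3 to 10, 3 to 8 and 2 to 11 lists, a correlation of 0.408 to 0.594, an overlap of 0 to 1, and a p of 0.0141 to 0.0970 near Kmt2d, 0.000451 to 0.0133 on chromosome 15, 7.77e-05 to 0.0318 near Kdm6a and 0.0151 to 0.153 on chromosome X. Lists moved most without KS1 1 (3 in KS1 and 2 in KS2 against KS1), KS1 4 (10 in KS1), KS1 3 and KS1 5 (11 each in KS2 against KS1), KS2 3 (7) and KS2 5 (8 in KS2). Kmt2d in KS1 lay between -0.28 and -0.07, in KS2 between -0.132 and 0.0874 (above 0 without WT 4 or KS2 3), and Kdm6a in KS2 between -0.0738 and 0.00977 (above 0 without WT 4). Of 896 gene and setting pairs of 29 named KS1 genes, 757 kept their call and 0 turned, and 11 genes never lost it. For 3 KS2 genes 53 of 87 pairs lost it, and for 24 genes of KS2 against KS1 151 of 696. The 29 KS1 genes include Rpl3-ps1, which the rule does not name. Rpl3 and Rpl3-ps1, whose separate values are uncertain, are among the 11. Depth of 20253866 counts or more recovered 18% of simulated 1.3-fold changes in KS1, so most changes of that size would be missed. A sex covariate was not run, because Xist was not analysed here and Y-linked genes were near 0 in all libraries.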

Other observations

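The test of a cell mixture shared by libraries, as coded, and the choice of the genes named here were made only after the values had been seen.

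Several genes outside the rule or lists, all chosen after their values were seen, were also called in KS1 by edgeR. Il4ra, the receptor chain for interleukin 4, rose in KS1 from 122 ± 26.6 to 230 ± 56.9 CPM (log2 fold change 0.92, edgeR adjusted p = 0.0327), with 131 ± 23.9 CPM in KS2. The surface antigen genes Ly6a (-1.06, edgeR adjusted p = 0.0463) and Ly6c1 (-0.94, edgeR adjusted p = 0.0169) fell in KS1, and both lie on chromosome 15. The nuclear envelope gene Sun2 (-0.27) and the Polycomb gene Cbx7 (-0.47) fell there too, and the focal adhesion kinase gene Ptk2 (0.65) and Amigo2 (0.94) rose.

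Other groupings of the libraries were drawn to ask whether chance gives as many genes. For KS1 against WT, 3 of 100 splits of the 10 libraries gave as many as 176, the real split included. That share is under the 5% set for this test, without adjustment over the 3 comparisons. The highest other split gave 738 genes. It set WT libraries 2 and 3 with KS1 libraries 1, 2 and 4 against the rest, and points to a structure of the samples that their group does not describe. Of these 10 libraries WT 2, WT 3, KS1 1 and KS1 2 had the highest macrophage marker sums (5791 to 8179 CPM, against 3109 to 5124 in the others) and the lowest pan-T cell sums (5180 to 5826 against 6351 to 7123 CPM). For KS2 against WT, 2 of 100 splits gave as many as 3 genes, the real split included, with 8 as the highest other. That share is also under 5% without adjustment over the 3 comparisons. It does not exclude chance, since the count of 3 genes fell to 0 on omission of most single libraries.

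The fold changes of the models correlated at 0.487. Shared WT libraries give such a correlation with no effect, and the covariance of 0.0547 lay above all 100 simulations of unchanged groups (0.0380 to 0.0541). Those simulations drew genes independently, while genes in the libraries vary together, so their range may be too narrow to judge this covariance. With the WT libraries split, the correlation was not positive in every split (-0.0761 to 0.176), so the shared libraries and a shared effect cannot be told apart. With B cell, macrophage and natural killer marker levels as covariates the correlation was 0.454. The bound of 0.1 set for this test was wrong, because shared WT libraries alone hold the correlation at 0.429 or above in simulation, so a shared variation in cell mixture stays open as well.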
